A study of Mus musculus with 2 samples.

How the data were processed

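Long-read RNA sequencing was done on adrenal gland tissue of C57BL/6J mice, in 1 group of 2 libraries that the labels number as biological replicates 1 and 2. Long-read RNA sequencing reads cDNA copies of RNA molecules from end to end, so that 1 read can be assigned to 1 transcript structure. The labels give the libraries separate biosamples that share 1 donor entry, so the spread between them is the spread between these samples and may in part be technical. One label field describes the tissue as male, while the field for sex was left as not collected and the age as unknown. The series holds no treatment, time or genotype, so no contrast between conditions was made.

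The authors deposited, for each library, a table of whole read counts per transcript model and an annotation of all models. Per the text deposited with each library, the counts were made on mouse genome mm10 with the GENCODE M21 annotation, from 1 alignment per library that followed an unfiltered one. Unannotated models are credited to TALON in the source column of the deposited annotation; TALON assigns each long read to an annotated or new transcript model. The sequencing platform, the aligner and any read correction are not given in the sources used here. The deposited counts are not normalized, each table lists only models with at least 1 read, and every count had a gene. Each model carries a class given by the authors: known (all splice junctions of an annotated transcript), incomplete splice match (ISM, a run of its junctions that lacks part of the transcript), NIC (known splice sites in an unannotated combination), NNC (at least 1 unannotated splice site), genomic (inside a gene without a matching splice structure), antisense and intergenic. The length in the deposited table is the annotated length for a known model and the length of the model otherwise, checked against the exon sums of the annotation with 0 mismatches in either library. Model ends are shared between reads and are not the ends of single reads. Coordinates are on mm10, counted from 1, and gene positions are those of the GENCODE annotation.

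Replicate 1 held 848782 reads and replicate 2 held 545229. A single read was worth 1.18 CPM (counts scaled to a total of 1000000 reads) in replicate 1 and 1.83 CPM in replicate 2. For a count of 0 a floor of 3 counts was set, which is 3.53 CPM and 5.50 CPM. Shares carry exact Clopper-Pearson and CPM values exact Poisson 95% confidence intervals. At a count of 0 the upper end of the Poisson interval is 4.35 and 6.77 CPM, above the floor. Intervals and floors cover counting error only. A fold against 0 reads was computed against 3 counts in that library and is a lower bound.

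Reads were summed per annotated gene and divided by all reads of the library, so ratios are on the scale of total reads. Genes with at least 10 reads summed over both libraries were tested with a two-sided Fisher's exact test of the reads of the gene against all other reads, with Benjamini-Hochberg adjustment and a threshold of 0.05. Under TMM or DESeq2 scaling and with the length trend removed, a two-sided exact binomial test took its place, with the same adjustment. It set the reads of replicate 2 against the share of the reads of the gene expected there. These tests compare the 2 libraries and not conditions, and they take reads as independent. Log2 ratios are of replicate 2 over replicate 1 after adding 1 CPM, which understates the difference of low genes. The common coefficient of variation came from edgeR (4.0.16, R 4.3.3) with TMM scaling, and DESeq2 (1.42.0) gave a further set of size factors. Python (3.11.15) with numpy (2.4.6), pandas (2.3.3) and scipy (1.17.1) served for the rest. Isoform use was compared with a two-sided Fisher's exact test of the most used known, NIC or NNC model against the other such models of a gene, over genes with at least 20 such reads in each library, with Benjamini-Hochberg adjustment. Unannotated models were matched between the libraries by chromosome, strand and all introns.

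The gene lists, the rule for the genes named and the first set of alternatives were fixed before the data were examined. The lists were steroidogenesis, cholesterol synthesis and supply, zona glomerulosa, zona fasciculata, X-zone, chromaffin cells of the medulla, capsule and stroma, endothelium, macrophage and immune, Schwann cells, adipocytes, kidney, erythroid cells, mitochondrial-encoded genes, immediate early and stress genes, antioxidant genes, imprinted genes and a sex chromosome check. Cyp11b1, Cyp11b2, Hsd3b6, Mc2r and Mrap stand in 2 lists each. The median log2 ratio of each list with at least 3 tested genes was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and a list was taken as shifted below percentile 2.5 or above 97.5. Nov, an older symbol of Ccn3, was not in the annotation. Nnt has 2 gene models of the same symbol and was left out of the tests and medians of its list.

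The genes named are the 10 of highest mean CPM, the 4 highest members of each list and those without a read, all members of the steroidogenesis list and the sex check, and the 10 called genes with the largest ratio in each direction at a mean of at least 50 CPM. For models, the rule took the 4 lowest shares of the most used model among steroidogenesis and among chromaffin genes, the 10 highest NIC or NNC models found in both libraries, the 10 highest genes with several isoforms, the 6 largest differences in isoform share and the 5 highest unannotated loci. Some genes that the rule takes are not reported here. Any other gene is named with the words that it was chosen after its values were seen.

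Alternatives were other scalings, count minimums, pseudocounts, transcript classes, fold and share limits, splice site tolerance, and each library on its own. After the values were seen, alternatives restricted to genes of 2000 to 4000 bases, corrected for the trend of the ratio with transcript length (medians of 30 bins of genes, interpolated on log2 length) or counting both gene models of Nnt were added. The length of a gene is the annotated length of its known transcripts, weighted by their reads in both libraries. Reads of other classes do not enter it. Over the lengths where the ratio rises, a gene sequenced mostly as shorter unannotated or incomplete models comes out low after the correction. A gene sequenced mostly as longer models comes out high.

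Each test was checked on simulated data. Those for the comparison of the libraries, the lists and the coefficient of variation were drawn from the real means and totals. For the comparison of the libraries over 9879 genes, Fisher's exact test recovered 35 of 100 genes changed 2-fold and 60 of 100 changed 4-fold, and called 0.0620% of the unchanged genes. With the length trend removed, the exact binomial test recovered 35 and 63 of 100 and called 0.0413%. A list of 15 genes raised 2-fold came out at percentile 100, and 3.5% of 200 unchanged lists fell outside the limits. All these counts were drawn with counting noise alone, without the coefficient of variation of 0.881 found between the libraries. The recoveries and the calls among unchanged genes and lists therefore describe counting noise only, not the spread between replicates. Against that spread, a list raised 2-fold need not leave the limits: the endothelial list had a median log2 ratio of 1.21 at percentile 82.7. The isoform test was checked on 2000 genes with random totals and shares that were not taken from the data. It recovered 76% of genes whose share was lowered by 20 percentage points and 99% of those lowered by 40. It called 0.278% of the unchanged. A simulated coefficient of variation of 0.5 came back as 0.499 over 9879 genes, with another common dispersion estimator of edgeR than the one used for the data.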

Results

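RNA of the mouse adrenal gland was read as long molecules in 2 libraries of C57BL/6J tissue, which the labels number as biological replicates of 1 group. The adrenal gland joins a steroid-producing cortex to a catecholamine-producing medulla. Replicate 1 held 848782 reads in 98236 transcript models and replicate 2 held 545229 reads in 86472. Of these models, 62.3% and 67.5% had a single read. The libraries differed in the length of what was read: known transcripts had a median annotated length per read of 1648 bases in replicate 1 and 2740 bases in replicate 2, and 44.0% against 5.47% of known reads came from transcripts under 1500 bases. At least 1 read was seen for 15239 annotated genes in replicate 1, for 13943 in replicate 2 and for 12437 in both. The 2802 genes seen only in replicate 1 had a median length of 1138 bases and the 1506 seen only in replicate 2 a median of 2433 bases, each with a median of 1 read.

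The most abundant genes were those of steroid synthesis. Star, which carries cholesterol to the inner mitochondrial membrane (chromosome 8, 25806555 to 25815982), had the highest mean, at 14093 CPM in replicate 1 and 28309 CPM in replicate 2 (mean 21201 ± 10052 SD, n = 2). The steroid 21-hydroxylase Cyp21a1 (chromosome 17, 34801348 to 34804561) followed at 15080.4 and 21791 CPM and was above Star in replicate 1. The 11-beta-hydroxylase Cyp11b1 (chromosome 15, 74834125 to 74841643) stood at 6662 and 16318 CPM, and the side-chain cleavage enzyme Cyp11a1 (chromosome 9, 58006411 to 58027023) at 8120 and 10190.2 CPM. Hsd3b1, the main 3-beta-hydroxysteroid dehydrogenase of the gland (chromosome 3, 98852194 to 98859794), stood at 11679 and 4561 CPM. The lipoprotein receptor Scarb1 (chromosome 5, 125277087 to 125341094), which takes up cholesterol esters, stood at 2242 and 10100.3 CPM. The rest of the 10 genes of highest mean level were the chaperone Hspa8 at 12116 and 9387 CPM, the chromaffin granule protein Chgb at 3881 and 14458 CPM, the ferritin light chain Ftl1 at 9921 and 789 CPM, and the fasciculata aldo-keto reductase Akr1b7 at 7103 and 2542 CPM.

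The 15 genes of the steroidogenesis list took 6.19% of the reads of replicate 1 (95% exact binomial interval 6.14 to 6.24) and 9.85% of those of replicate 2 (9.78 to 9.93), a mean of 8.02% ± 2.59 (SD, n = 2). In Fisher's exact test between the libraries with Benjamini-Hochberg adjustment, 9 of the 15 were higher in replicate 2, 4 were lower and 2 did not pass, against 14 that passed when adjusted over the list alone. Among the higher were Star (2.01-fold), Cyp11b1 (2.45-fold), Scarb1 (4.50-fold), Cyp21a1 (1.44-fold), the electron donors Fdxr (1269 and 2755 CPM) and Por (143 and 1166 CPM), and Nr5a1, the transcription factor that sets steroidogenic identity (113 and 943 CPM). Cyp11a1 was 1.25-fold higher on the total-read scale and lower once TMM scaling was used (log2 ratio 0.33 against −0.11). The largest difference was that of the aldosterone synthase Cyp11b2, at 54.2 CPM (46 reads) and 1548 CPM (844 reads), 28.6-fold. The lower genes were Hsd3b1 (2.56-fold), the ferredoxin Fdx1 (1959 and 603 CPM, 3.25-fold), and the corticotropin receptor Mc2r (73.0 and 38.5 CPM) with its accessory protein Mrap (244 and 25.7 CPM). Hsd3b6 (140.2 and 185 CPM) and Nr0b1 (6 reads in each library) did not pass the test over all genes. Under TMM scaling 8 of the list were higher and 5 lower. Removal of the length trend left 8 higher and 4 lower: Fdx1 and Hsd3b6 were then higher, Star, Cyp11b1 and Cyp11a1 lower, and Mc2r and Mrap did not pass. Hsd3b1 with Hsd3b6 and Cyp11b1 with Cyp11b2 are close paralogs, so reads that were assigned between them are uncertain.

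**Figure D1:**
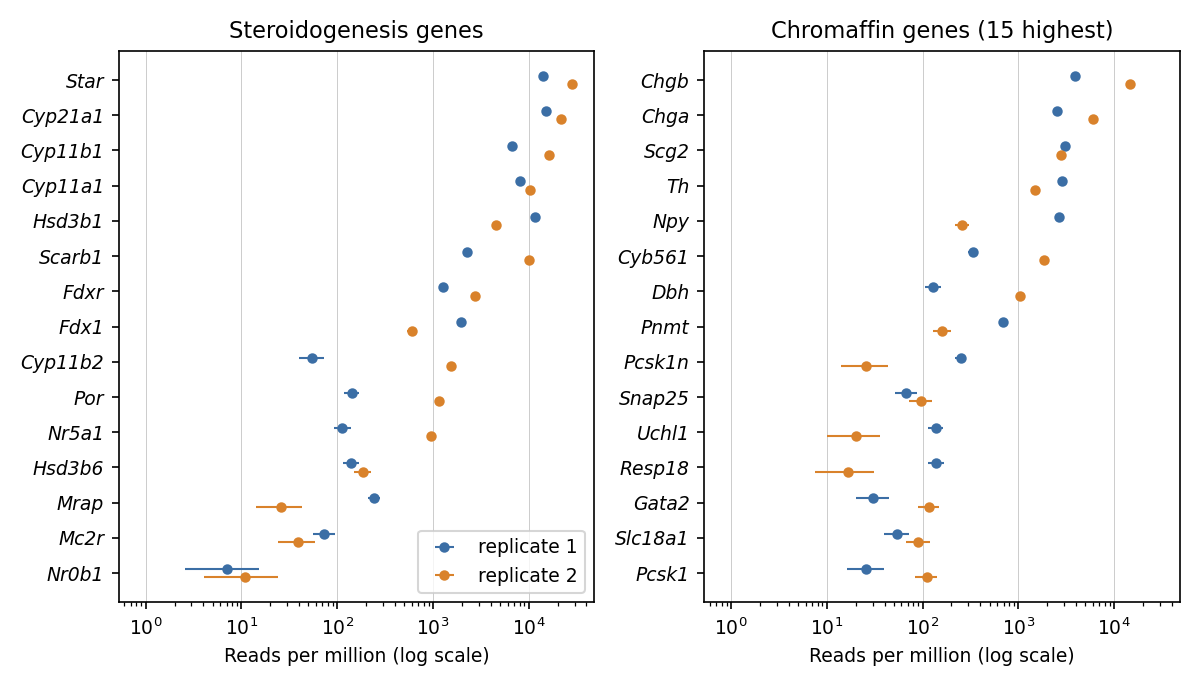
Level in CPM (log axis) of the 15 steroidogenesis genes and the 15 highest chromaffin genes in replicate 1 (blue) and replicate 2 (orange), 1 point per library with its exact Poisson 95% interval, which covers counting error only and is hidden by the point where narrow. Star ran from 14093 to 28309 CPM, while Cyp11b2 ran from 54.2 to 1548 CPM and Npy from 2680 down to 257 CPM.

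Genes of the cortical zones and of cholesterol supply were read in both libraries. In the zona glomerulosa list, which took 0.111% and 0.349% of reads, 6 of 11 tested genes were higher in replicate 2, 2 were lower and 3 did not pass, and 8 passed when adjusted over the list alone. Under TMM scaling 4 were higher and 2 lower, and with the trend of the ratio with transcript length removed 5 and 4. After Cyp11b2 its highest members were the angiotensin receptor Agtr1a (141 and 835 CPM), the potassium channel Kcnk3 (479.5 and 381 CPM) and Dab2 (137 and 237 CPM), and Ccn3 had no read in either library. Of the 5 zona fasciculata genes, which took 1.47% and 1.97%, Cyp11b1 and the transporter Abcb1b (606 and 776 CPM) were higher in replicate 2, and Akr1b7, Mrap and Mc2r were lower. All 5 passed when adjusted over the list alone, and Abcb1b did not pass after TMM scaling. With the length trend removed none of the 5 kept its call in the same direction: Akr1b7 was higher (log2 ratio 0.88), Abcb1b (−1.03) and Cyp11b1 (−0.24) were lower, and Mrap and Mc2r did not pass. The X-zone is a transient inner layer of the mouse cortex. Its markers Akr1c18 and Pik3c2g had no read in either library, where the upper end of the Poisson interval is 4.35 and 6.77 CPM. Thrb (16 and 12 reads) did not pass, also when adjusted over the list alone.

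Of the 25 genes of cholesterol synthesis and supply, 13 were higher in replicate 2, 4 were lower and 8 did not pass, with 17 past the threshold when adjusted over the list alone; the list took 0.281% and 0.552% of reads. Under TMM scaling 10 were higher and 6 lower, and with the length trend removed 5 were higher and 6 lower. Its highest member was Dhcr7, the last enzyme of one branch of cholesterol synthesis, at 180.3 and 1790.1 CPM (9.93-fold, adjusted p = 2.77e-236 in Fisher's exact test). The acyltransferase Soat1, which stores cholesterol as esters, stood at 495 and 574 CPM and the sterol oxidase Msmo1 at 439 and 517 CPM, and neither passed. The synthase Hmgcs1 stood at 120.2 and 473 CPM and was higher in replicate 2.

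Chromaffin genes of the medulla took 1.73% of the reads of replicate 1 (1.70 to 1.76) and 2.88% of those of replicate 2 (2.83 to 2.92), a mean of 2.30% ± 0.811 (SD, n = 2). Of 28 tested, 12 were higher in replicate 2, 12 were lower and 4 did not pass, against 25 past the threshold when adjusted over the list alone. Under TMM scaling 7 were higher and 13 lower, and with the length trend removed 7 and 6 of 27. The granule proteins Chgb (3.73-fold) and Chga (2558 and 5985 CPM) were higher in replicate 2, while Th, the rate-limiting enzyme of catecholamine synthesis (2831 and 1489 CPM), and the granin Scg2 (3062 and 2786 CPM) were lower. Among members chosen after their values were seen, the noradrenaline-forming Dbh (2552 bases) was 7.95-fold higher at 130 and 1031 CPM, whereas the neuropeptide Npy (566 bases) was 10.4-fold lower and Pnmt, which makes adrenaline (1154 bases), 4.35-fold lower. Once the length trend was removed, Dbh stayed higher, Npy did not pass and Pnmt was higher in replicate 2 (log2 ratio 0.66).

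Markers of other cell types were present at low levels. Capsule and stroma genes took 0.0578% and 0.0444% of reads; 4 of 9 were higher in replicate 2, 1 was lower and 5 passed when adjusted over the list alone. Under TMM scaling 2 were higher and 2 lower, and with the length trend removed 0 were higher and 2 lower of 8. The stromal proteoglycan Dcn stood at 369 and 86.2 CPM, Col1a2 at 31.8 and 67.9, and Rspo3 at 58.9 and 40.4, Nr2f2 had 35 and 30 reads, and Gli1 had no read. Endothelial genes took 0.0603% and 0.154%; 7 of 11 were higher, 2 were lower and 9 passed when adjusted over the list alone, with Plvap at 96.6 and 389 CPM, Eng at 63.6 and 255, Tie1 at 14.1 and 269.6 and Flt1 at 54.2 and 134. Under TMM scaling 5 of the endothelial genes were higher and 3 lower, and with the length trend removed 3 and 1. Macrophage and immune genes took 0.197% and 0.0442%; 9 of 12 were lower in replicate 2, 3 were higher and all 12 passed when adjusted over the list alone. With the length trend removed 1 was higher and 0 were lower. Their highest members were Lyz2 (648 and 141 CPM), H2-Ab1 (325 and 33.0), H2-Aa (298 and 33.0) and Cd74 (184 and 66.0).

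Erythroid genes took 0.193% and 0.0160% of reads; 4 of 5 were lower in replicate 2, 1 with the length trend removed, and 5 passed when adjusted over the list alone. Hbb-bs stood at 696 and 58.7 CPM, Hba-a1 at 608 and 38.5, Hba-a2 at 514 and 27.5 and Hbb-bt at 93.1 and 3.67. The paired globin genes are near-identical copies whose split is uncertain. Of the adipocyte genes, 3 of 4 were lower in replicate 2, 2 with the length trend removed, and 4 passed when adjusted over the list alone. Plin1 had 72 and 23 reads, Cfd 85 and 0, Cidec 14 and 2 and Adipoq 14 and 0, and Lep and Ucp1 had none. Schwann cell genes summed to 9 and 10 reads. Among them Sox10 had 1 and 2, Cdh19 2 and 1 and S100b 2 and 0, while Foxd3 and Erbb3 had none. No gene of this list passed, also when adjusted over the list alone. The 10 kidney genes had 1 read in all, of Lrp2 in replicate 1, and Umod, Kap, Slc34a1, Aqp2, Nphs1, Slc12a1, Slc12a3 and Slc22a6 had none, so no kidney gene was tested. In the sex check, Xist had no read in either library, and the Y-linked Ddx3y (44.8 and 205.4 CPM), Eif2s3y (69.5 and 119 CPM), Uty (3 and 6 reads) and Kdm5d (2 and 5 reads) were read in both. Ddx3y and Eif2s3y were higher in replicate 2 and both passed when adjusted over the list alone; under TMM scaling 1 of them passed.

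Mitochondrial-encoded genes took 0.0935% of the reads of replicate 1 and 0.00422% of those of replicate 2. All 8 tested were lower in replicate 2, as they were when adjusted over the list alone, and 2 were lower with the length trend removed. The highest was mt-Co1 at 596 and 25.7 CPM, followed by mt-Nd2 (74.2 and 3.67), mt-Nd5 (61 and 0 reads, at least 13.1-fold lower) and mt-Nd4 (58.9 and 3.67), and mt-Atp8 and mt-Nd4l had no read. Antioxidant genes took 0.691% and 0.172%; 8 of 11 were lower in replicate 2, 2 were higher and 11 passed when adjusted over the list alone. Once the length trend was removed, 3 were higher and 2 lower. Prdx1 stood at 3836 and 106 CPM, Prdx3 at 865 and 240.3, Gstm1 at 659.8 and 114 and Gpx4 at 482 and 44.0. Immediate early and stress genes took 0.132% and 0.358%; 6 of 8 were higher in replicate 2 and 2 were lower, and all 8 passed when adjusted over the list alone. With the length trend removed 4 were higher and 0 lower. Jun stood at 452 and 1410.4 CPM, the orphan nuclear receptor Nr4a1 at 164 and 994, Junb at 417 and 330.1 and the chaperone Hspa1a, whose near-identical copy is Hspa1b, at 21.2 and 493. Of the 6 imprinted genes tested, 3 were higher, 2 were lower and 5 passed when adjusted over the list alone. Corrected for the length trend, 1 was higher and 2 were lower. Meg3 stood at 169.7 and 576 CPM, Ndn at 569 and 163, Cdkn1c at 378 and 112 and Grb10 at 30.6 and 64.2, and H19 and Zim1 had no read.

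Known transcripts took nearly the same share of reads in both libraries, 72.5% and 72.5% (mean 72.5% ± 0.0192 SD, n = 2). Incomplete matches took 11.9% and 9.79%, NIC models 3.08% and 6.08%, NNC models 2.55% and 4.67%, genomic models 4.66% and 3.33%, antisense models 4.41% and 2.07% and intergenic models 0.822% and 1.57%. The exact binomial intervals of the 2 libraries did not overlap for any of these 6 classes. A single intergenic locus on chromosome 13 held 0.186% and 1.15% of all reads, so the larger intergenic share of replicate 2 rests on that locus. Among incomplete reads, those that kept the 3′ part of the transcript were 45.6% in replicate 1 and 61.7% in replicate 2, and those that kept the 5′ part 43.2% and 27.5%. Protein-coding genes held 91.5% and 94.8% of reads and processed pseudogenes 1.34% and 0.232%.

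**Figure D2:**
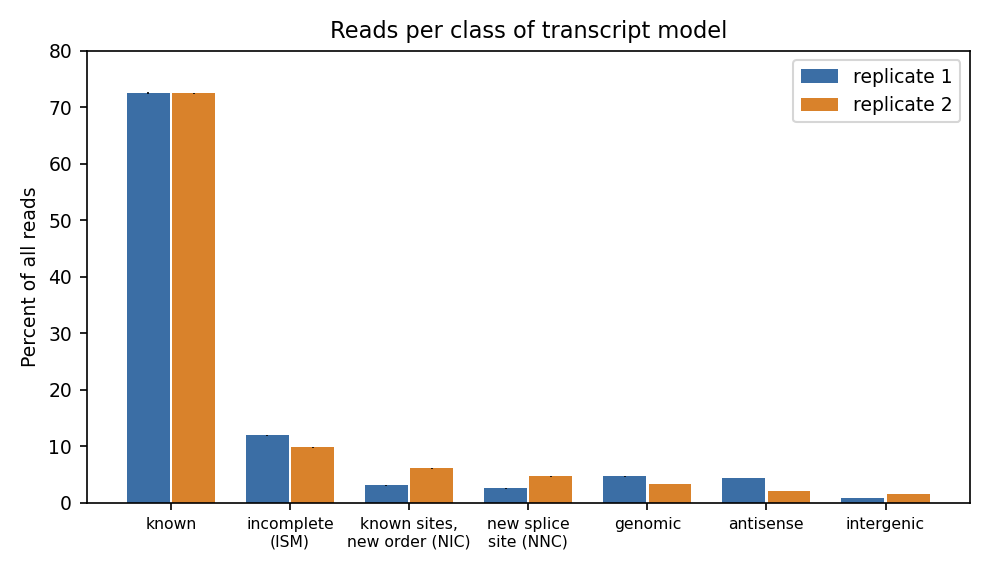
Percent of all reads (vertical axis, from 0) in each class of transcript model, in replicate 1 (blue) and replicate 2 (orange), with exact binomial 95% intervals that are narrower than the lines drawn. Known transcripts held 72.5% in both libraries, and the NIC and NNC classes were larger in replicate 2 than in replicate 1.

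The levels of genes correlated between the libraries with Pearson r = 0.677 (bootstrap 95% interval over genes 0.670 to 0.685) and Spearman rho = 0.687 across 16745 genes, which are not independent replicates. Over the 9879 genes with at least 10 reads summed, r was 0.359 (0.342 to 0.378) and rho 0.330. The common coefficient of variation between replicates beyond counting noise was 0.881 over the same 9879 genes. Of these, 6363 (64.4%) differed between the libraries in Fisher's exact test with Benjamini-Hochberg adjustment, 3611 higher and 2752 lower in replicate 2. The median log2 ratio of all tested genes was 0.38 and TMM scaling offset replicate 2 by 0.43 on that scale, so the split depended on the scaling: 56.8% of called genes were higher on the total-read scale, 45.0% under TMM (2731 of 6069) and 44.8% under DESeq2 size factors (2715 of 6059).

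Short transcripts were lower in replicate 2 and long ones higher, and the trend turned at both ends. The median log2 ratio was −2.81 for genes under 500 bases, −3.48 for 500 to 1000, −2.41 for 1000 to 1500, −0.61 for 1500 to 2000, 0.76 for 2000 to 2500, 1.36 for 2500 to 3000, 1.45 for 3000 to 4000, 1.19 for 4000 to 6000 and 0.63 for 6000 bases or more, and Spearman's rho between ratio and length was 0.57 across 9166 genes. Genes called higher had a median length of 3142 bases and genes called lower 1372 bases. After the length trend was removed, an alternative chosen after the values were seen, 3786 of 9166 genes differed, 1806 higher and 1980 lower, and 2770 of them were also called without the correction. Relative to genes of their length, Hsd3b1 (−0.74), Star (−0.35), Cyp11b1 (−0.24) and Cyp11a1 (−0.13) were lower in replicate 2 on the log2 scale. Cyp11b2 (5.89), Nr5a1 (1.65), Por (1.72), Fdx1 (1.46) and Scarb1 (0.99) were higher. The value of Hsd3b1 is uncertain, since its length of 1722 bases rests on 7 known reads in replicate 1 and 6 in replicate 2. That of Fdx1 is uncertain too, since 1 length of 984 bases was used in both libraries. Its form Fdx1-202 of 2759 bases held 1.20% of its known, NIC and NNC reads in replicate 1 and 31.0% in replicate 2.

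**Figure D3:**
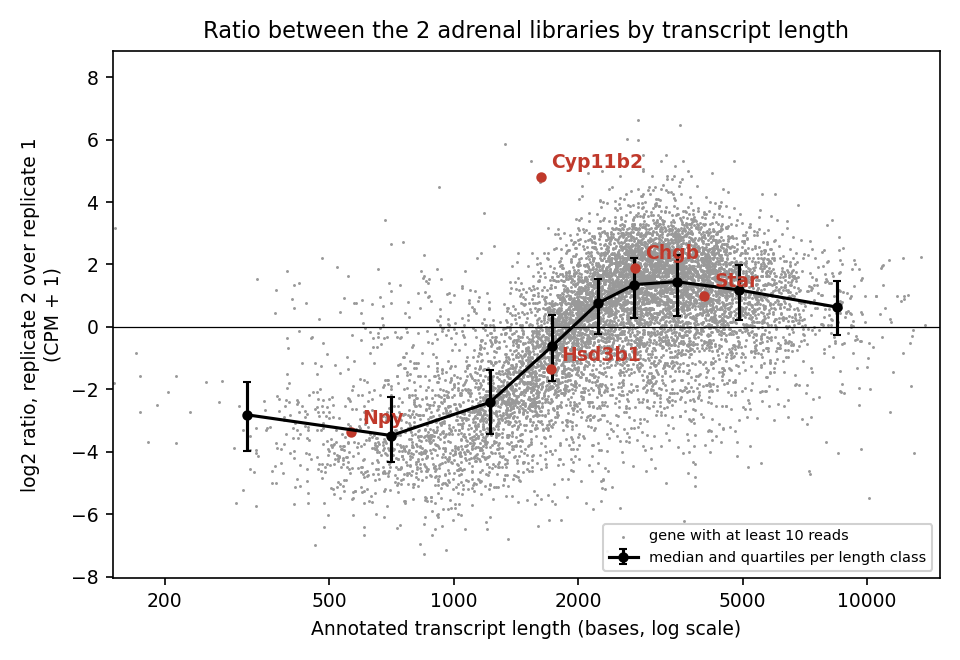
Log2 ratio of replicate 2 over replicate 1 (vertical axis, CPM + 1) against the annotated transcript length in bases (log axis), 1 grey point per gene with at least 10 reads, with the median and quartiles of each length class in black. The medians rose from −3.48 at 500 to 1000 bases to 1.45 at 3000 to 4000 bases, with −2.81 under 500 bases and 0.63 from 6000 bases up, and Cyp11b2 (4.81 at 1625 bases) stood above the genes of its length.

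The genes with the largest ratios followed length in part. Of the 10 with the lowest ratio, 9 had 463 to 1353 bases, where the running median of the log2 ratio lay between −3.52 and −2.13, and 1 of the 10 was also among the 10 lowest relative to genes of its length, against 4 of the 10 highest. Higher in replicate 2 were Txnip, an inhibitor of thioredoxin (9 and 620 reads, 107-fold), the water channel Aqp1 (1 and 77 reads), Chtf8 (1 and 74), the glucose transporter Slc2a1 (1 and 54), Serinc3 (14 and 302, 33.6-fold), the plasminogen activator Plat (6 and 124, 32.2-fold) and Cyp11b2. Gm28006 (5 and 1015 reads) lies inside the long noncoding RNA Neat1 on the same strand, and Gm45837 (4 and 228) overlaps Arap1 and Pde2a, so the gene of origin of these reads is uncertain. Lower in replicate 2 were Timm17b (122 and 0 reads, at least 26.1-fold), Ifi27l2a (107 and 0, at least 22.9-fold), Rps19bp1 (105 and 0, at least 22.5-fold), Gm17018 (94 and 0, at least 20.1-fold), Chchd1 (86 and 0, at least 18.4-fold), the adipsin gene Cfd (at least 18.2-fold), the histone H2afz (624 and 4) and Ndufb10 (473 and 3). Mrps6 (130 and 0, at least 27.8-fold), which overlaps Slc5a3, and Hypk (343 and 1), which overlaps Serf2, are uncertain in the same way.

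As groups, 5 lists lay outside the limits set by 10000 random lists of matched expression, all toward lower levels in replicate 2. The median log2 ratio was −3.85 for mitochondrial-encoded genes (percentile 0.01), −3.14 for macrophage and immune genes (0.04), −3.95 for erythroid genes (0.615), −3.02 for adipocyte genes (1) and −2.53 for antioxidant genes (2.4, and 3.1 with the 2 gene models of Nnt entered). A pseudocount of 10 CPM left 4 lists outside, without the adipocyte list (median −1.18, percentile 4.86), and known transcripts alone left 3. The genes of these lists were short, with median lengths from 697 bases for the erythroid to 1501 bases for the adipocyte list. With the length trend removed, their percentiles were 3.41, 32.6, 27.5, 3.33 and 50.3 in the same order. The only list outside the limits was then steroidogenesis (median 0.87, percentile 99.1, against 0.57 and 71.5 without the correction). Both medians are the values of Nr0b1, the middle gene of the list, which had 6 reads in each library. Its neighbours after the correction were Cyp21a1 (0.16) and Hsd3b6 (0.95), so the size of this shift depends on a gene with few reads. The other lists lay inside the limits, with medians of 0.63 for cholesterol synthesis and supply (percentile 68.2), 0.79 for zona glomerulosa (68.8), −0.91 for zona fasciculata (27.0), 0.10 for chromaffin genes (28.8), 0.79 for capsule and stroma (66.8), 1.21 for endothelium (82.7), 1.74 for immediate early and stress genes (95.7) and 0.53 for imprinted genes (59.1). X-zone, Schwann cell, kidney and sex check lists had too few tested genes for a median.

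Several isoforms were in use for a minority of genes. At least 2 known, NIC or NNC models each held 10% or more of the reads of these classes in both libraries for 459 of 2251 genes (20.4%). Among the most abundant of these, by all reads of the gene, were Hsd3b1, most of whose reads lay in incomplete models outside these classes, Scg2, Hspa5, Fdxr, Pkm, Sqstm1, Ddx5, Acly and Cyb561. Pkm, the pyruvate kinase of muscle and most other tissues, was read as Pkm-201 in 70.1% and 71.2% of its reads of these classes. Pkm-202 held 26.0% and 23.3% of them. Of the reads of these classes for its gene, Hspa5-201 held 82.2% and 80.7% and Sqstm1-202 75.3% and 74.4%. Counted the same way, Ddx5-201 held 69.1% and 54.3% and Acly-201 72.2% and 60.4%. For Star the single transcript Star-201 held 97.9% and 97.9% of the reads of these classes.

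The lowest shares of a most used model in the steroidogenesis list belonged to Hsd3b1 (an NNC model with 45.0% and 27.3% of its 149 and 44 reads of these classes), Fdxr-201 (74.6% and 74.7%), Nr5a1-201 (75.9% and 73.7%) and Fdx1-201 (97.0% and 67.3%). Fdx1-202, a form of 2759 bases beside the 875 bases of Fdx1-201, held 1.20% and 31.0% of the reads of these classes for Fdx1 (adjusted p = 1.32e-44 for the share of Fdx1-201 in Fisher's exact test). In the chromaffin list they belonged to Cyb561, where a NIC model of 6 exons (chromosome 11, 105933702 to 105940164) held 43.8% and 59.1%, Scg2-201 (62.6% and 42.4%, the rest mostly Scg2-202), Snap25-202 (84.4% and 85.1%) and Dbh-201 (81.6% and 87.9%).

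Isoform use differed between the libraries in 215 of 2186 genes (9.84%) in Fisher's exact test with Benjamini-Hochberg adjustment. In 158 of the 215 (73.5%, 67.1 to 79.3) the longer side held the larger share in replicate 2. The 6 largest differences followed this in part. Sbsn-203 (732 bases) fell by 89.7 percentage points from 93.6% to 3.92%, with Sbsn-201 (2221 bases) at 96.1% in replicate 2. Sin3b-202 (1024 bases) held 96.2% and 19.2%. The retained-intron forms Ddx24-204 (87.3% and 0%), Eif2s2-203 (83.2% and 8.70%) and Kif1b-209 (78.4% and 7.14%) were lower in replicate 2, 2 of them longer than the coding form of the gene in second place (Ddx24-201, 2850 bases, and Eif2s2-201, 2542 bases). Hsp90aa1-202 held 12.5% and 84.8% of 24 and 33 reads.

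Incomplete models were left out of these shares, and for 148 of 2803 genes (5.28%) a spliced incomplete model found in both libraries was the most used of all. Hsd3b1 was the most abundant of them. Its most used model had 4 exons, with 8718 of 9542 spliced reads in replicate 1 (91.4%) and 1848 of 2107 in replicate 2 (87.7%). This model has the splice junctions of exons 2 to 5 of Hsd3b1-202 and begins in an exon at 98858152 to 98858341 of chromosome 3. Its last exon runs past the annotated 3′ end at 98852194, to 98849570 in replicate 1 and 98851150 in replicate 2. These are ends of models, not of single reads. The annotated first exon lies upstream at 98859672 to 98859794, and 0.126% (0.0650 to 0.220) and 0.332% (0.134 to 0.683) of spliced reads lay in models that started upstream of the most used one. Other genes of this kind, chosen after their values were seen, were Hao2, with a 5-exon model lacking the 5′ end at 62.8% and 70.3% of spliced reads, Dhcr7 (51.7% and 73.4%), and Hsp90ab1, with a model lacking the 3′ end at 83.2% and 2.95%.

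**Figure D4:**
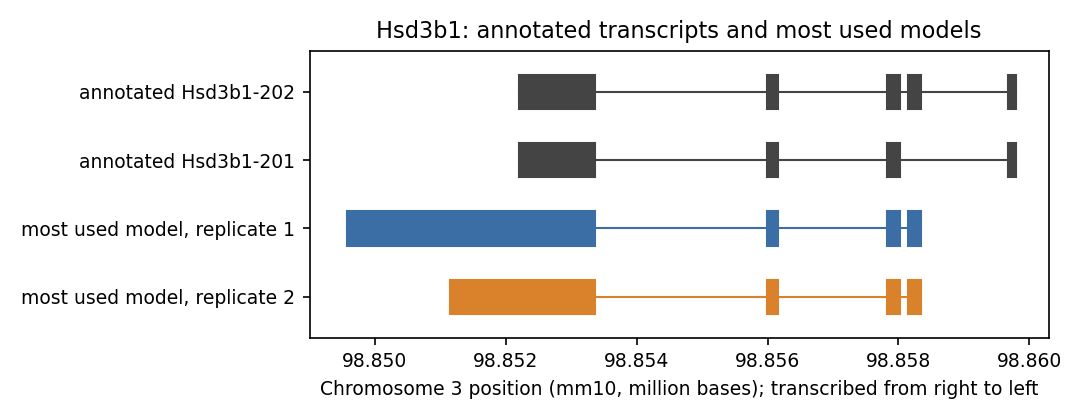
Map of Hsd3b1 on chromosome 3 of mm10 (horizontal axis in megabases, transcribed from right to left), with exons as boxes and introns as lines, for the 2 annotated transcripts (grey) and the most used model of replicate 1 (blue) and replicate 2 (orange). The most used models start in the exon at 98858152 to 98858341 and lack the annotated first exon, and their 3′ ends are ends of models, not of single reads.

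Spliced models outside the annotation recurred between the libraries. Models were counted in each library and summed, so that a model with enough reads in both counts in each. Of 11259 NIC or NNC models with at least 2 reads, 5028 (44.7%, 43.7 to 45.6) had the same introns in the other library. The interval takes all entries as independent, which models counted in each library are not. By library the share was 46.2% of 5043 models of replicate 1 and 43.4% of 6216 models of replicate 2. For known spliced transcripts the share was 77.8% of those of replicate 1 and 83.1% of those of replicate 2. The known transcripts were not matched on reads, and among NIC or NNC models with at least 5 reads the share was 72.6%. Counted once each and at any number of reads, 4868 models were found in both, 3040 NIC and 1828 NNC. The most abundant was a 5-exon NIC model of the antizyme Oaz1, a regulator of polyamine synthesis (chromosome 10, 80826656 to 80829284), with 3420 and 35 reads, 94.5% and 85.4% of the reads of the gene. Others were the model of Cyb561 named above (103 and 561 reads), a NIC model of the phosphate carrier Slc25a3 (87 and 379), an NNC model of the chaperonin Cct6a that held 75.8% and 78.3% of its gene, and a pair of NIC models of Hnrnpk with 36.9% and 35.4%, and 27.0% and 24.6%. Also among the first 10 were NIC models of Fdxr (156 and 158), Cyp11a1 (48 and 214) and Oaz2, where it held 82.3% and 90.8% of the gene.

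Of the loci outside annotated genes, the most abundant in both libraries was intergenic, on the plus strand of chromosome 13 from 55184447 to 55189154, with 1578 and 6272 reads (0.186% and 1.15% of all reads). It lies 15688 bases from Fgfr4 and 20628 bases from Nsd1. Intergenic loci were also read on chromosome 14 from 32115639 to 32120457 between Oxnad1 and Msmb (322 and 694 reads) and on chromosome 5 from 135623607 to 135627838, 4780 bases from Rhbdd2 (332 and 460 reads). The remaining 2 of the first 5 were single-exon loci antisense to annotated genes: 1 on chromosome 4 from 155557959 to 155559267 against Gnb1 (1476 and 5 reads), and 1 on chromosome 2 from 26136814 to 26138383 against the pseudogene Tmem250-ps (1235 and 11 reads).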

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

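Alternatives that use genes of 2000 to 4000 bases, that remove the length trend or that count both models of Nnt were chosen after the values were seen. For the counts of genes differing between the libraries, 3978 passed with at least 50 reads summed, 2835 among genes of 2000 to 4000 bases and 3786 with the length trend removed, each over fewer genes than the 9879 (4772, 4223 and 9166), and other scalings, filters and a fold limit kept the count between 5520 and 6281. Pearson r was 0.661 with a pseudocount of 10 CPM, 0.359 over genes with at least 10 reads summed, 0.568 for known transcripts only and 0.741 for genes of 2000 to 4000 bases. The coefficient of variation ran from 0.677 for genes of 2000 to 4000 bases to 1.05 for known transcripts only. At least 10 reads in both libraries left 5169 genes detected, and genes of 2000 to 4000 bases made up 4986. Known transcripts were 75.5% of reads without the genomic class. Lists outside the random limits numbered 3 with known transcripts only and 1 with the length trend removed, and the cause of the former was not tested.

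Genes with several isoforms numbered 208 with a share of 20%, 160 with 50 reads in each library, and 1224 in replicate 2 and 1236 in replicate 1 alone, where neither a model nor 20 reads need recur in the other library. The genes measured were 2251, 868, 3618 and 4224 in the same order. Isoform use differed in 742 of 2759 genes (26.9%) when incomplete models were counted and in 114 of 855 (13.3%) with 50 reads in each library, against 215 of 2186 (9.84%). Unannotated spliced models were found in both libraries in 17.6% of cases with at least 1 read, 72.6% with at least 5 reads and 59.4% when splice sites were matched within 10 bases. The shares of steroidogenesis and chromaffin genes moved by less than their spread with reads of known genes only, without mitochondrial-encoded genes and with known transcripts only. Leaving out 1 of 2 libraries must move a mean by less than the spread, so these 6 settings say nothing. In all 27 other settings of these results moved less than that spread or 1.5 times the count, and of the single lists 60 settings kept their side of the limits, 9 lost it and 1 gained it, and no list outside the limits turned its direction. Correlation, coefficient of variation and tests between libraries cannot be had from 1 library. No paired analysis was possible because the series has 1 group. At this depth 62.3% and 67.5% of the models had a single read, and differences in such models were not detectable.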

Other observations

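Of the tests in this part, the one that leaves out the 50 most abundant genes was set before its result was seen and decides nothing, and the others were chosen afterwards. Hsd3b1 and Cyp11b2 were also picked as patterns after their values were seen, and the genes named here lie outside the rule fixed in advance unless they were named above. The series has 1 group, so no explanation that sets groups apart was tested, and the only biological one tested was the share of zona glomerulosa tissue, for Cyp11b2.

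Some genes of the early response to stimulation stood above genes of their length in replicate 2, though their list did not as a whole, and endothelial genes went both ways. On the length-adjusted log2 scale Hspa1a, an inducible chaperone, stood at 3.10 with 18 and 269 reads, Fos at 2.54 with 13 and 58 reads and Nr4a1 at 1.41, while Jun, Junb, Egr1 and Ier2 did not pass with the length trend removed, and the immediate early and stress list as a whole lay at percentile 92.3. Of the 11 endothelial genes, Tie1, Plvap and Pecam1 were called higher with the length trend removed, at 2.799, 1.70 and 1.54, Emcn was called lower at −1.79 and the other 7 passed in neither direction, and the list lay at percentile 91.0. Aqp1, a gene of no list, stood at 4.74. The imprinted noncoding RNA Meg3 stood at 2.95 while the imprinted Ndn stood at −3.22 and Cdkn1c at −1.50, so members of that list parted. Gas1, a growth arrest protein of the cell membrane, had 14 and 119 reads (6.32). The length of 1183 bases behind this value is shorter than its gene (chromosome 13, 60174405 to 60177365), so the value is too high if longer forms were read. Beside the loci named above, a spliced locus antisense to Tacc1 was read on chromosome 8 from 25154552 to 25158031 with 436 and 122 reads.

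Of the reads antisense to genes, 2.38% in replicate 1 and 4.98% in replicate 2 were spliced and the rest had a single exon. Of the single-exon ones, 27.9% and 22.2% had an edge within 50 bases of the 3′ end of the opposite gene, against 7.70% and 13.1% near its 5′ end (3.62-fold and 1.69-fold). Counted over models in place of reads, the same ratios were 1.63-fold and 2.00-fold. This was the pattern first weighed beside the other ones, and its values did not decide what these reads came from.

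Genes under 1000 bases and genes of 2000 to 4000 bases differed by 4.56 in their median log2 ratio between the libraries. A few abundant genes shift the ratios of all other genes by 1 amount at any length, which leaves no difference between the classes, against 4.56 here (bootstrap 95% interval over genes 4.43 to 4.70). That value is the pattern itself, seen before the prediction was written, so this is a deduction and not a separate test. A difference in total reads acts through low counts, yet among genes with at least 100 reads summed the medians differed by 5.20 (5.06 to 5.36). Drawing equal totals (4.67) and leaving out the 50 most abundant genes (4.55) decide nothing, since neither could have ended it in counts scaled to totals. Selection of molecules by length, at a different size in each library, is a candidate explanation that also predicts a shift within genes, and the longer side held more of replicate 2 in 73.5% of the 215 genes with differing isoform use (67.1 to 79.3). That shift does not set selection apart from other causes that act by molecule length, and no such other cause was tested. Whether short molecules were lost from replicate 2 or long ones from replicate 1 stays open as well.

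Cyp11b2 was 4.81 higher in replicate 2 on the log2 scale at an annotated 1625 bases, percentile 99.7 of 783 genes of like length. Its known model held 734 of 844 reads in replicate 2, but 108 of the other 110 (6 of 18 in replicate 1) lay in models that end over 1000 bases beyond the annotated 3′ end. Of these, 3 in each replicate reach into the paralog Cyp11b1. Part of the RNA in replicate 2 may thus be longer: the most read of these models had 3770 bases (43 reads) and the most read at the most common end 2694 bases (19 reads). Among 1138 and 1271 genes of these lengths its ratio still stood at percentiles 99.5 and 99.4, against medians of 1.42 and 1.33, so length alone leaves the excess. A larger share of zona glomerulosa in the tissue of replicate 2 could not be told apart from its absence: the length-adjusted median of the 10 other genes of that list was −0.14 at percentile 41.3, with members from −4.71 (Wnt4) to 2.66 (Shh) and 5 above 0. Regulation of Cyp11b2 itself and reads shared with Cyp11b1 also stay open, as untested.

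The most used model of Hsd3b1 lacked the annotated first exon in both libraries. Incomplete copying at the rate of genes of its annotated length is not a candidate explanation. Of spliced known and incomplete reads, 99.8% and 99.2% lacked the 5′ end in Hsd3b1. The medians were 2.44% and 2.08% in 191 and 62 genes within 10% of its annotated length of 1722 bases and with at least 100 such reads. The most used models of Hsd3b1 end beyond its annotated 3′ end, and genes of the length of these models were not compared. All of the genes compared had a lower share than Hsd3b1. A start of transcription in the second annotated exon may account for it, as may a stop of copying particular to this RNA, and neither was tested.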
